A study of Caenorhabditis elegans with 14 samples.

How the data were processed

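Whole young adult worms were collected 3 days after hatching from bleach-synchronised cultures at 20 °C, per the labels' protocols, and total RNA was extracted with TRIzol, treated to remove DNA and made into libraries with the KAPA Hyper Prep kit. Mutants were kept as heterozygotes over a balancer chromosome with a GFP marker, and homozygous P0 and F1 worms were picked by hand, per the labels. The null allele has a stop codon in exon 1 of mbd-2, and the tagged control strain carries GFP and FLAG sequence inserted at position 6064091 of chromosome I, per the labels. The coiled-coil allele removes that domain from the tagged protein. The labels give 1 batch date for the null table and another for the coiled-coil table, so batch and allele cannot be told apart.

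The authors deposited 2 tables of TPM values, a unit in which each gene is normalised for its length and each library for its total. The submitters' processing notes name cutadapt, fastp, STAR 2.7.9a, RSEM 1.3.3 and the genome build WBcel235; their roles, the annotation release and whether strand was used are not given in the sources used here. TPM keeps no depth, so no counting interval or detection floor is given, and a gene at 0 is only listed at 0. All 46926 gene identifiers matched the WBcel235 annotation used here for names and positions, and 44115 of them have a name. No column of values was left unused.

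The groups were compared as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using an empirical Bayes fit with a trend in the variance and Benjamini-Hochberg adjustment at 0.05. Genes at 1 TPM or more in at least 2 libraries of a table were tested. The 3 groups of a table were fitted together, and the tables, which were normalised separately, were fitted apart. Fold changes on this scale understate the change of genes near 1 TPM. Whether the null and the coiled-coil effects differed was tested as a contrast of the 2 within-table effects over genes tested in both tables. Replicates were compared before averaging, and the lowest Pearson's r between replicates of a group was 0.973. No pair of libraries held identical values.

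Gene lists were tested against other genes with camera at a preset correlation of 0.01 and an estimated one, adjusted over the lists of a comparison. The 30 lists, fixed from textbook knowledge, were NuRD and MEC complex, synMuvB and DREAM, P granule and germ plasm, oocyte and eggshell, sperm and spermatogenesis, major sperm proteins, meiosis, early embryo zygotic genes, vitellogenins, histones, cuticle collagens, moulting-cycle cuticle genes, antimicrobial and immune response, intracellular pathogen response, heat shock, endoplasmic reticulum and mitochondrial unfolded protein responses, detoxification, DAF-16 targets, fatty acid metabolism, neuronal genes, neuropeptides, muscle, intestine, germline small RNA pathway, histone methylation and demethylation, ribosomal proteins, oxidative phosphorylation, vulva and egg laying, and adult-stage cuticle. Of the listed symbols, 13 were not in the annotation, and lists share some members. Families of at least 15 genes with the same name stem, the chromosomes, and genes within 500 kb of mbd-2 (Fisher's exact test, two-sided) were also tested.

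The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. After mbd-2, the rule names in each comparison with a control the 6 named genes with the largest log2 fold change up and the 6 down, and 2 up and 2 down that have only a sequence name, among genes that passed, reached a mean of 5 TPM in a group and had no overlap between libraries. It adds up to 4 members with the smallest adjusted p from each list that camera called, of which some are given here. For F1 against P0 and for the contrasts between alleles it names 4 up and 4 down. The antisense gene models were chosen after their values were seen, as models with at least 90% of their exonic bases opposite to a gene with a mean of at least 200 TPM in both controls. The male marker genes are outside the rule as well.

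Alternatives were a pseudocount of 0.1, no filter on low values, a mean of at least 5 TPM, median-of-ratios factors, quantile normalization, a fit of only the groups compared, a replicate block, a log2 fold change of at least 1, leaving out each library in turn, fry for the lists, and, chosen after seeing the data, removal of ribosomal RNA with rescaling. Unchanged groups set against the same controls were simulated 20 times to give the chance similarity of comparisons that share a control. The limma step was tested on simulated data with 50 genes per fold size among 15805 genes of the null and 15519 of the coiled-coil table. For a log2 change of 0.5 it recovered 40, 38, 50 and 40% in P0 null, F1 null, P0 deletion and F1 deletion worms. It called 0.0256, 0.0449, 0.0457 and 0.0588% of unchanged genes. Real data had far more calls, hence a looser cutoff, so these rates do not carry over.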

Results

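RNA of whole young adult Caenorhabditis elegans was measured in 14 libraries, to ask how worms without the methyl-CpG-binding domain protein MBD-2, or with MBD-2 lacking its coiled-coil domain, differed from their controls. The null table held 6 libraries: 2 of N2 wild type, 2 of P0 null worms and 2 of F1 null worms. The coiled-coil table held 8 libraries: 3 of a control strain with GFP-tagged MBD-2, 3 of P0 and 2 of F1 worms whose tagged MBD-2 lacked the coiled-coil domain. P0 worms were homozygous mutants with heterozygous parents, and F1 worms were homozygous mutants with homozygous parents. Each library listed TPM values for 46926 genes, a unit that keeps no sequencing depth. Genes at 1 TPM or above numbered 11522 to 11589 in N2, 14155 to 14223 in P0 null and 14481 to 14518 in F1 null worms. In the coiled-coil table they numbered 10953 to 11022 in the tagged control, 14051 to 14180 in P0 and 14298 to 14608 in F1 deletion worms. Ribosomal RNA took 13.6 ± 1.18% of TPM in N2, 5.03 ± 0.342% in P0 null and 2.42 ± 0.649% in F1 null worms (SD, n = 2 each). Its share was 9.90 ± 0.946% in the tagged control and 3.43 ± 0.497% in P0 deletion worms (SD, n = 3 each), and 3.83 ± 1.64% in F1 deletion worms (SD, n = 2). Nothing stated that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

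The mbd-2 gene (WBGene00023409) has 4 exons at I, 6064088 to 6065298 on the plus strand of WBcel235, and lies inside pigo-1 on the minus strand, with 11 exonic bases in common. The null allele carries a stop codon in exon 1. mbd-2 stood at 41.8 ± 3.90 TPM in N2, 8.59 ± 0.495 TPM in P0 null and 5.55 ± 1.01 TPM in F1 null worms (SD, n = 2 each). It fell in P0 null worms by 2.16 on the log2(TPM + 1) scale (SE 0.14, limma adjusted p = 9.54e-05) and in F1 null worms by 2.72 (SE 0.14, limma adjusted p = 4.33e-05). The tagged control held 45.8 ± 1.27 TPM and P0 deletion worms 36 ± 2.09 TPM (SD, n = 3 each), against 28.1 ± 3.27 TPM in F1 deletion worms (SD, n = 2). Log2 fold changes in the coiled-coil table were -0.34 in P0 (SE 0.08, limma adjusted p = 0.00421) and -0.69 in F1 worms (SE 0.09, limma adjusted p = 0.000179). mbd-2 was lower in F1 than in P0 worms, with log2 fold changes of -0.56 in the null table and -0.35 in the coiled-coil table (limma adjusted p = 0.0142 for each). The F1 against P0 calls for mbd-2 were lost under median-of-ratios scaling, which left -0.26 and -0.23. In the coiled-coil table the call was lost as well in a fit of only the groups compared (-0.35). They were also lost when P0 null replicate 2 (-0.51), F1 null replicate 1 (-0.40) or F1 deletion replicate 2 (-0.24) was left out.

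**Figure D1:**
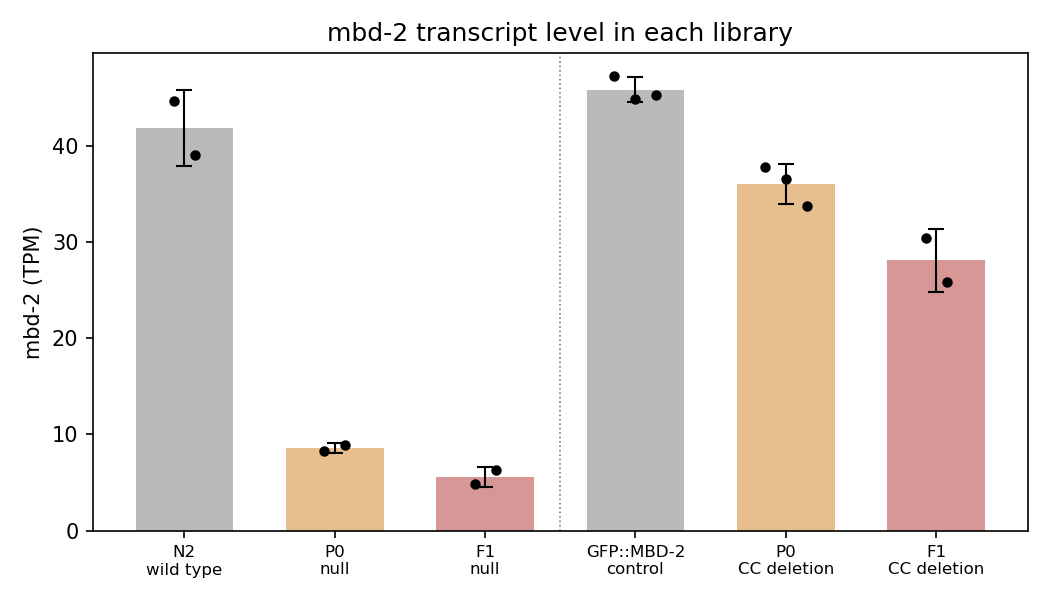
Level of mbd-2 in TPM (y axis) in each of the 6 groups (x axis); bars are group means, error bars SD, dots single libraries, and the dotted line separates the tables. Group means fell from 41.8 to 5.55 TPM in the null table and from 45.8 to 28.1 TPM in the coiled-coil table.

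P0 null worms, compared with N2, had far less yolk protein mRNA and more mRNA of moulting-cycle cuticle, neuronal and histone genes. The vitellogenin vit-3, which encodes a yolk protein, fell from 4387 ± 281 TPM in N2 to 59 ± 54.5 TPM (SD, n = 2 each). The cuticle collagen col-165 rose from 0.59 TPM in both N2 libraries to 283 ± 6.68 TPM (SD, n = 2), and the cuticlin cut-2 from 1.07 ± 0.424 to 363 ± 38.5 TPM. The histone H1-like gene hil-7 rose from 5.36 ± 1.90 to 807 ± 71.1 TPM. Their log2 fold changes on the log2(TPM + 1) scale were -6.57 (SE 0.68, limma adjusted p = 0.000502) for vit-3, 7.48 (SE 0.10, 8.09e-06) for col-165, 7.47 (SE 0.58, 0.000185) for cut-2 and 7.02 (SE 0.25, 2.51e-05) for hil-7.

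All 6 vitellogenins fell in P0 null worms (6 adjusted over the list alone). A median log2 fold change of -3.99 gave camera adjusted p = 6.21e-08, and adjusted p = 0.335 with an estimated correlation. Members included vit-1 (31.1 ± 20.6 against 2381 TPM), vit-4 (107 ± 92.5 against 3830 TPM) and vit-5 (1100 ± 242 against 6227 TPM). Of 24 moulting-cycle cuticle genes, 21 rose and none fell (21 adjusted over the list alone). The median was 4.10 (camera adjusted p = 0.000589, adjusted p = 0.366 with an estimated correlation). Among them the collagens dpy-10 (87.4 ± 0.332 against 3.44 TPM), dpy-7 (60.9 ± 2.62 against 0.555 TPM) and dpy-17 (744 ± 11.4 against 13.4 TPM), and the moulting gene mlt-9 (26.1 ± 1.58 against 0.25 TPM), rose. Neuronal genes rose in 34 of 35 cases (34 adjusted over the list alone), among them the syntaxin unc-64, the calcium channel subunit egl-19 and the transcription factor unc-86 (14.9 ± 1.21 against 0.795 TPM). Their median, 1.66, gave camera adjusted p = 6.33e-06 and adjusted p = 0.361 with an estimated correlation. Neuropeptide genes rose in 111 cases and fell in 4, with 14 not passing (113 and 6 adjusted over the list alone), with the insulin-like genes ins-7 at 57.6 ± 1.3 against 2.62 TPM and ins-11 at 15.2 ± 2.92 against 0.17 TPM. At a median 1.52, camera gave adjusted p = 0.000514, and adjusted p = 0.553 with an estimated correlation. Histone genes rose in 52 and fell in 1 of 69 (53 and 1 adjusted over the list alone). A median of 2.43 gave camera adjusted p = 0.00600, and adjusted p = 0.376 with an estimated correlation. The histone genes his-14 (WBGene00001884, 321 ± 17.3 against 1.57 TPM) and his-9 (WBGene00001899, 208 ± 34.3 against 2.22 TPM) share their names with near-identical copies, so the values of single copies are uncertain.

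Vulva and egg-laying genes rose in 29 of 32 cases and none fell (29 adjusted over the list alone), led by hbl-1 (89.3 ± 10.4 against 2.72 TPM). The median was 1.62 (camera adjusted p = 0.000589, adjusted p = 0.335 with an estimated correlation). The intracellular pathogen response list, made of pals and related genes, had 19 of 25 higher and none lower (19 adjusted over the list alone), for example pals-26 at 5.59 ± 1.35 against 0.035 TPM. Their median, 1.27, gave camera adjusted p = 0.0436 and adjusted p = 0.366 with an estimated correlation. Early embryo zygotic genes rose in 16 of 23 (16 adjusted over the list alone; median 1.23), but the list test did not pass (camera adjusted p = 0.0851; adjusted p = 0.490 with an estimated correlation). P granule and germ plasm genes fell in 11 and rose in 2 of 19 (11 and 2 adjusted over the list alone), with the Vasa helicase glh-1 at 111 ± 3.20 against 179 TPM. At a median -0.19, camera gave adjusted p = 4.66e-08, and adjusted p = 0.335 with an estimated correlation. Oocyte and eggshell genes fell in 9 and rose in 3 of 28 (7 and 2 adjusted over the list alone), or 27 and 1 under median-of-ratios scaling, the yolk receptor rme-2 going from 428 to 314 ± 24.1 TPM. A median of -0.05 gave camera adjusted p = 4.38e-07, and adjusted p = 0.335 with an estimated correlation. None of 30 major sperm protein genes passed in either direction (0 adjusted over the list alone; limma; median -0.15; camera adjusted p = 2.23e-06 for lower; adjusted p = 0.490 with an estimated correlation), and quantile normalization made 10 of them lower. Of 122 cuticle collagens, 69 rose and 34 fell (the same adjusted over the list alone). The median was 1.04 (camera adjusted p = 0.0550 toward lower, adjusted p = 0.430 with an estimated correlation). The named genes outside these lists that fell were 1 copy of pud-2.2 (WBGene00017490, 3.27 ± 2.09 against 142 TPM), the lectin clec-97 (0.41 ± 0.170 against 37.4 TPM), T13F3.6 (1.56 ± 0.849 against 414 TPM) and Y47G6A.33 (5.20 ± 3.74 against 174 TPM). The other gene named pud-2.2 (WBGene00017500) did not pass, with 3.27 against 58.4 TPM (limma adjusted p = 0.592). For 2 genes named nspc-2, 1 was listed at 0 against 46.5 TPM (WBGene00044337) and the other at 62.6 TPM against 0 (WBGene00044357), so reads may have been shared out differently between copies. Named genes that rose were col-74 (185 ± 10.6 TPM), cut-3 (249 ± 17.1 TPM), tts-2 (352 ± 43.2 TPM), F41F3.3 (876 ± 101 TPM) and C02E7.6 (537 ± 51.7 TPM), each at 1.70 TPM or below in N2.

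By limma, 9470 of 15805 genes were higher and 1316 lower in P0 null worms than in N2, with a median log2 fold change of 0.44 over all genes. Of these, 4783 were higher and 456 lower by a log2 fold change of at least 1. The split depended on scaling: median-of-ratios factors gave 6330 higher and 3787 lower (median 0.12), and quantile normalization 4188 higher and 5397 lower (median -0.10). Simulated recovery of log2 changes of 1 and 2 was 62 and 86%.

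F1 null worms, compared with N2, had very high levels of sperm transcripts and lower levels of oocyte and yolk transcripts. All 30 major sperm protein genes, which encode the cytoskeletal and signalling proteins of nematode sperm, rose (30 adjusted over the list alone). Their median, 6.44, gave camera adjusted p = 4.86e-05 and adjusted p = 0.567 with an estimated correlation. msp-33 rose from 5.52 ± 3.62 to 514 ± 5.37 TPM, msp-45 from 2.90 ± 2.41 to 461 ± 2.37 TPM and msp-3 from 2.31 ± 1.82 to 308 ± 4.64 TPM (SD, n = 2 each). Of 34 sperm and spermatogenesis genes, 31 rose and 1 fell (31 and 1 adjusted over the list alone). At a median 3.30, camera gave adjusted p = 2.55e-05, and adjusted p = 0.376 with an estimated correlation. All 28 oocyte and eggshell genes fell (28 adjusted over the list alone). A median of -0.66 gave camera adjusted p = 5.99e-13, and adjusted p = 0.374 with an estimated correlation. These directions held under median-of-ratios, quantile and ribosomal-RNA-removed scaling.

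The sperm genes that rose included msd-2 (195 ± 7.77 TPM, listed at 0 in N2), the myosin VI gene spe-15 (42.4 ± 4.14 against 3.19 TPM), spe-26 (15.4 ± 0.127 against 0.285 TPM) and smz-2 (63.4 ± 1.34 against 1.01 TPM). The spermatogenesis Argonautes alg-3 (34.5 ± 2.77 against 0.27 TPM; log2 fold change 4.82, limma adjusted p = 2.96e-05) and alg-4 (38.7 ± 3.43 against 0.395 TPM; 4.85, 3.51e-05) rose as well. Among the oocyte genes, the eggshell permeability genes perm-2 (199 ± 20.8 against 1310 TPM) and perm-4 (243 ± 18.8 against 1197 TPM), and the oocyte maturation gene oma-2 (183 ± 2.45 against 354 TPM), fell. All 6 vitellogenins fell (6 adjusted over the list alone), vit-3 to 22.7 ± 3.01 TPM (log2 fold change -7.54, SE 0.68, limma adjusted p = 0.000279) and vit-5 to 318 ± 32.1 TPM. The median was -4.86 (camera adjusted p = 0.000128, adjusted p = 0.376 with an estimated correlation). P granule and germ plasm genes fell in 12 and rose in 4 of 19 (12 and 4 adjusted over the list alone), meg-1 going from 80.2 ± 3.64 to 21.7 ± 0.184 TPM. Their median, -0.36, gave camera adjusted p = 0.000318 and adjusted p = 0.376 with an estimated correlation. Early embryo zygotic genes fell in 12 and rose in 4 of 23 (12 and 4 adjusted over the list alone), with the T-box gene tbx-9 at 12 ± 0.827 against 25.9 TPM. At a median -0.65, camera gave adjusted p = 0.000995, and adjusted p = 0.376 with an estimated correlation.

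In F1 null worms 8 of 10 NuRD and MEC complex genes fell and 1 rose (8 and 1 adjusted over the list alone). A median of -0.29 gave camera adjusted p = 0.00222, and adjusted p = 0.376 with an estimated correlation. The histone chaperone lin-53 (149 ± 1.07 against 206 TPM) and the deacetylase hda-1 (94.5 ± 0.382 against 124 TPM) were among them. Of 19 synMuvB and DREAM genes, 15 fell (15 adjusted over the list alone). The median was -0.42 (camera adjusted p = 1.36e-06, adjusted p = 0.374 with an estimated correlation). Histone methylation and demethylation genes fell in 19 and rose in 3 of 34 (19 and 3 adjusted over the list alone). Their median, -0.24, gave camera adjusted p = 4.86e-05 and adjusted p = 0.374 with an estimated correlation. In P0 null worms, where a scaling decided the direction, 10 of 10 NuRD and MEC genes were higher (10 adjusted over the list alone). At a median 0.32, and -0.07 under median-of-ratios scaling, camera gave adjusted p = 0.133, and adjusted p = 0.490 with an estimated correlation. Likewise 9 synMuvB and DREAM genes were higher and none lower in P0 null worms (6 adjusted over the list alone; median 0.16), against 1 higher and 10 lower under median-of-ratios scaling (camera adjusted p = 0.558; adjusted p = 0.735 with an estimated correlation). Histone methylation genes in P0 null worms were 23 higher and 0 lower by limma (23 adjusted over the list alone), against 9 higher and 11 lower under median-of-ratios scaling. Camera gave adjusted p = 0.480, and adjusted p = 0.655 with an estimated correlation.

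Several other lists were called higher in F1 null worms, while vulva and egg-laying and moulting-cycle cuticle genes did not pass (camera adjusted p = 0.297 and 0.925; adjusted p = 0.596 and 0.963 with an estimated correlation). Neuropeptide genes rose in 111 and fell in 4 cases, with 14 not passing (113 and 4 adjusted over the list alone). The median was 1.59 (camera adjusted p = 1.36e-06, adjusted p = 0.512 with an estimated correlation). Neuronal genes rose in 32 and fell in 1 of 35 (33 and 1 adjusted over the list alone). Their median, 1.1, gave camera adjusted p = 0.000152 and adjusted p = 0.376 with an estimated correlation. Muscle genes rose in 25 and fell in 2 of 30 (25 and 2 adjusted over the list alone), with the myosin heavy chain myo-3 at 77.2 ± 2.25 against 18 TPM. At a median 0.80, camera gave adjusted p = 0.0238, and adjusted p = 0.649 with an estimated correlation. Antimicrobial and immune response genes rose in 31 and fell in 2 of 40 (31 and 2 adjusted over the list alone), among them the infection response gene irg-5 (2251 ± 107 against 45.6 TPM) and the lysozyme ilys-3 (50.2 ± 8.41 TPM, listed at 0 in N2). A median of 1.2 gave camera adjusted p = 0.0238, and adjusted p = 0.376 with an estimated correlation. Histone genes rose in 48 and fell in 6 of 69 (48 and 6 adjusted over the list alone). The median was 2.23 (camera adjusted p = 0.00131, adjusted p = 0.376 with an estimated correlation). Ribosomal protein genes rose in 74 and fell in 1 of 78 (74 and 1 adjusted over the list alone). Their median, 0.39 against 0.32 for all genes, gave camera adjusted p = 0.000122 and adjusted p = 0.596 with an estimated correlation. Cuticle collagens rose in 78 and fell in 19 of 122 (79 and 20 adjusted over the list alone), col-39 reaching 489 ± 161 against 1.59 TPM. At a median 1.69, camera gave adjusted p = 0.0573, and adjusted p = 0.400 with an estimated correlation. Intracellular pathogen response genes rose in 17 and fell in 1 of 25 (17 and 1 adjusted over the list alone), a direction that quantile normalization turned to 6 higher and 8 lower. Camera gave adjusted p = 0.0330, and adjusted p = 0.376 with an estimated correlation. The nematode-specific peptide genes nspa-5 (584 ± 172 TPM) and nspa-1 (349 ± 160 TPM), each with near-identical copies, were listed at 0 in N2, while C50F7.5 rose to 1127 ± 166 TPM and F08B4.8 to 375 ± 17.9 TPM. Genes that fell included the acyl-CoA dehydrogenase acdh-2 (0.04 against 33.8 TPM), sri-40 (1.28 ± 0.460 against 53.5 TPM), clec-97 (0.97 ± 0.240 TPM), T13F3.6 (0.30 ± 0.212 TPM) and F15E6.4 (1.26 ± 1.05 against 201 TPM).

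In F1 null worms limma called 7828 of 15805 genes higher and 3796 lower than in N2 (median log2 fold change of all genes 0.32), of which 4815 and 753 changed by a log2 of at least 1. Median-of-ratios scaling gave 7658 higher and 4202 lower, and quantile normalization 4316 and 7050 (median -0.20). Simulated recovery of log2 changes of 1 and 2 was 58 and 86%.

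F1 null worms, set against P0 null worms, had more sperm transcripts: all 30 major sperm protein genes rose (30 adjusted over the list alone). The median was 6.81 (camera adjusted p = 2.17e-14, adjusted p = 0.367 with an estimated correlation). Sperm and spermatogenesis genes rose in 30 of 34 cases, with 1 lower (30 and 1 adjusted over the list alone). Camera gave adjusted p = 2.21e-14, and adjusted p = 0.367 with an estimated correlation. Moulting-cycle cuticle genes were lower in F1 in 16 and higher in 3 of 24 (17 and 3 adjusted over the list alone), and the collagen dpy-14 went from 642 ± 16 TPM in P0 to 0.325 ± 0.0636 TPM in F1 (SD, n = 2 each; log2 fold change -8.92, limma adjusted p = 2.91e-05). At a median -3.54, camera gave adjusted p = 0.00914, and adjusted p = 0.408 with an estimated correlation. Early embryo zygotic genes were lower in 22 of 23 (22 adjusted over the list alone). A median of -1.69 gave camera adjusted p = 0.000123, and adjusted p = 0.367 with an estimated correlation. Oocyte and eggshell genes were lower in 27 of 28 (27 adjusted over the list alone). The median was -0.59 (camera adjusted p = 0.000123, adjusted p = 0.367 with an estimated correlation). Neuronal genes were lower in 23 of 35 and higher in none (23 adjusted over the list alone). Their median, -0.48, gave camera adjusted p = 0.0134 and adjusted p = 0.492 with an estimated correlation. Ribosomal protein genes were higher in 72 and lower in 1 of 78 (72 and 1 adjusted over the list alone). At a median 0.34, camera gave adjusted p = 1.65e-15, and adjusted p = 0.402 with an estimated correlation. col-165 (0.105 ± 0.0212 TPM), col-74 (0.04 ± 0.0566 TPM) and hil-7 (4.97 ± 1.36 TPM) were lower in F1 than in P0, although cuticle collagens as a list were called higher (56 higher and 35 lower of 122; 57 and 36 adjusted over the list alone; median 0.80; camera adjusted p = 0.000162; adjusted p = 0.367 with an estimated correlation). msp-31 rose from 1.65 ± 0.332 to 452 ± 2.93 TPM. In all, limma called 3317 genes higher and 7730 lower in F1 than in P0 (median -0.28), a split that became 4957 higher and 4478 lower under median-of-ratios scaling (median 0.02).

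In P0 coiled-coil deletion worms, compared with the tagged control, yolk and oocyte transcripts were lower and moulting-cycle cuticle, neuronal and neuropeptide transcripts higher. The vitellogenin vit-1 fell from 2747 ± 62.4 to 49.5 ± 28.7 TPM, while hil-7 rose from 0.443 ± 0.675 to 517 ± 34.6 TPM and dpy-14 from 1.22 ± 0.915 to 440 ± 47.1 TPM (SD, n = 3 each). Log2 fold changes were -5.90 (SE 0.35, limma adjusted p = 2.36e-06) for vit-1, 8.58 (SE 0.27, 1.82e-07) for hil-7 and 7.71 (SE 0.26, 2.28e-07) for dpy-14. All 6 vitellogenins fell (6 adjusted over the list alone). A median of -3.70 gave camera adjusted p = 7.50e-07, and adjusted p = 0.316 with an estimated correlation.

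Oocyte and eggshell genes fell in 25 and rose in 1 of 28 in these P0 worms (25 and 1 adjusted over the list alone), for example egg-5 (81.8 ± 2.02 against 167 TPM) and rme-2 (315 ± 8.3 against 619 TPM). The median was -0.54 (camera adjusted p = 1.78e-15, adjusted p = 0.342 with an estimated correlation). P granule and germ plasm genes fell in 17 and rose in 1 of 19 (17 and 1 adjusted over the list alone), with pgl-3 at 89 ± 1.3 against 148 TPM. Their median, -0.54, gave camera adjusted p = 2.93e-11 and adjusted p = 0.316 with an estimated correlation. Meiosis genes fell in 20 and rose in 3 of 35 (20 and 3 adjusted over the list alone). At a median -0.19, camera gave adjusted p = 1.38e-07, and adjusted p = 0.381 with an estimated correlation. SynMuvB and DREAM genes fell in 10 and rose in 1 of 19 (10 and 1 adjusted over the list alone). A median of -0.21 gave camera adjusted p = 1.36e-05, and adjusted p = 0.381 with an estimated correlation. Neuropeptide genes rose in 116 cases and fell in 1, with 12 not passing (117 and 1 adjusted over the list alone), nlp-8 going from 5.35 ± 0.0458 to 61.4 ± 1.64 TPM. The median was 2.02 (camera adjusted p = 1.03e-08, adjusted p = 0.316 with an estimated correlation). Neuronal genes rose in 34 of 35 and fell in 1 (34 and 1 adjusted over the list alone), among them the proprotein convertase egl-3 (150 ± 12.8 against 28.4 TPM). Their median, 2.12, gave camera adjusted p = 2.96e-06 and adjusted p = 0.492 with an estimated correlation. Moulting-cycle cuticle genes rose in 23 and fell in 1 of 29 (23 and 1 adjusted over the list alone), with the collagen sqt-3 at 499 ± 59.2 against 2.46 TPM. At a median 2.90, camera gave adjusted p = 0.00273, and adjusted p = 0.316 with an estimated correlation. Intracellular pathogen response genes rose in 24 and fell in 1 of 25 (24 and 1 adjusted over the list alone). A median of 1.53 gave camera adjusted p = 0.00176, and adjusted p = 0.316 with an estimated correlation. Vulva and egg-laying genes rose in 27 and fell in 2 of 32 (28 and 2 adjusted over the list alone). The median was 1.60 (camera adjusted p = 0.00229, adjusted p = 0.316 with an estimated correlation). Major sperm protein genes rose in 19 of 28 (19 adjusted over the list alone; median 1.25), with no pass for the list (camera adjusted p = 0.492; adjusted p = 0.920 with an estimated correlation), and their summed level was 51.2 TPM against 2.13 TPM in the control. In the null table, a separate batch, the sum was higher, at 121 TPM in N2 and 74.3 TPM in P0 null worms. Histone genes rose in 45 and fell in 3 of 69 (45 and 3 adjusted over the list alone). Their median, 1.32, gave camera adjusted p = 0.111 and adjusted p = 0.316 with an estimated correlation. Cuticle collagens rose in 74 and fell in 26 of 136 (74 and 26 adjusted over the list alone). At a median 0.92, camera gave adjusted p = 0.687, and adjusted p = 0.927 with an estimated correlation. Early embryo zygotic genes were higher in 13 and lower in 4 of 23 (13 and 4 adjusted over the list alone), turning to 7 higher and 13 lower under quantile normalization. A median of 0.75 gave camera adjusted p = 0.790, and adjusted p = 0.920 with an estimated correlation. Other named genes that rose were tts-2 (302 ± 62.2 TPM), col-167 (208 ± 86.8 TPM) and F41F3.3 (673 ± 272 TPM), each under 1 TPM in the control, and ilys-3 (211 ± 34.9 TPM), col-165 (202 ± 61.2 TPM) and C02E7.6 (274 ± 60.9 TPM) were listed at 0 there. Those that fell were the folate transporter folt-2 (8.75 ± 3.07 against 277 TPM), T13F3.6 (1.91 ± 0.789 against 284 TPM), and clec-209 (11.7 ± 2.89 against 334 TPM) and pud-2.2 (WBGene00017500, 24.2 ± 24.8 against 532 ± 253 TPM), which have near-identical copies. The other pud-2.2 copy, WBGene00017490, fell as well (49.6 against 408 TPM, limma adjusted p = 0.00270). The call for the first copy (log2 fold change -5.52, limma adjusted p = 0.0226) was lost without P0 deletion replicate 2 (-3.81), without control replicate 2 (-5.18) or 3 (-5.46), and with a pseudocount of 0.1 (-6.65).

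By limma, 8364 of 15519 genes were higher and 2411 lower in P0 deletion worms (median log2 fold change 0.44), 5260 and 330 of them by a log2 of at least 1. Median-of-ratios scaling gave 7324 higher and 3913 lower (median 0.30), and quantile normalization 4299 higher and 5698 lower (median -0.07). Simulated recovery of log2 changes of 1 and 2 was 82 and 94%.

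F1 coiled-coil deletion worms had high sperm and cuticle collagen transcripts and low yolk and oocyte transcripts. All 28 major sperm protein genes rose (28 adjusted over the list alone), and msp-59 rose from 0.0933 ± 0.0950 TPM in the control (SD, n = 3) to 300 ± 159 TPM (SD, n = 2). The median was 6.87 (camera adjusted p = 2.71e-07, adjusted p = 0.545 with an estimated correlation). Of 136 cuticle collagens, 111 rose and 10 fell (111 and 10 adjusted over the list alone). Their median, 3.20, gave camera adjusted p = 5.74e-07 and adjusted p = 0.545 with an estimated correlation. dpy-5 rose from 0.02 ± 0.0346 to 320 ± 159 TPM and col-73 from 0.03 ± 0.0520 to 432 ± 211 TPM, with log2 fold changes of 8.20 (SE 0.26, limma adjusted p = 5.48e-07) and 8.63 (SE 0.30, 7.60e-07). All 6 vitellogenins fell (6 adjusted over the list alone). At a median -4.38, camera gave adjusted p = 1.03e-06, and adjusted p = 0.376 with an estimated correlation.

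The 2 F1 deletion libraries differed in size of effect: the collagen median was 3.48 with 115 higher without F1 replicate 1, and 2.88 with 106 higher without F1 replicate 2. Sperm and spermatogenesis genes rose in 27 and fell in 2 of 31 (27 and 2 adjusted over the list alone), including spe-11 (18.4 ± 7.69 against 0.0633 TPM). A median of 2.44 gave camera adjusted p = 0.000280, and adjusted p = 0.545 with an estimated correlation. msp-81 (168 ± 82.8 TPM), msp-45 (133 ± 66.9 TPM) and msp-40 (193 ± 106 TPM) were listed at 0 in the control. Moulting-cycle cuticle genes rose in 28 of 29 (28 adjusted over the list alone), among them the collagens dpy-13 (270 ± 142 against 0.0467 TPM) and sqt-2 (27.9 ± 1.31 against 0.183 TPM). The median was 2.71 (camera adjusted p = 1.11e-06, adjusted p = 0.376 with an estimated correlation). Oocyte and eggshell genes fell in 27 of 28 (27 adjusted over the list alone), with the eggshell gene cbd-1 at 731 ± 33.0 against 1159 TPM. Their median, -0.54, gave camera adjusted p = 3.25e-15 and adjusted p = 0.376 with an estimated correlation. P granule and germ plasm genes fell in 15 and rose in 1 of 19 (15 and 1 adjusted over the list alone). At a median -0.41, camera gave adjusted p = 3.78e-07, and adjusted p = 0.376 with an estimated correlation. Histone genes rose in 43 and fell in 5 of 69 by limma. SynMuvB and DREAM genes fell in 11 of 19 (10 adjusted over the list alone). Camera gave adjusted p = 1.11e-06, and adjusted p = 0.376 with an estimated correlation. NuRD and MEC genes fell in 6 of 10 with 1 higher (7 and 1 adjusted over the list alone). For the list, camera's adjusted p = 0.00250 became adjusted p = 0.493 with an estimated correlation. Histone methylation genes fell in 21 of 34 with 3 higher (21 and 3 adjusted over the list alone). Camera gave adjusted p = 8.39e-07, and adjusted p = 0.419 with an estimated correlation. Neuropeptide genes rose in 114 cases and fell in 4, with 11 not passing (117 and 4 adjusted over the list alone). At a median 1.78, camera gave adjusted p = 2.46e-08, and adjusted p = 0.376 with an estimated correlation. Neuronal genes rose in 33 and fell in 1 of 35 (33 and 1 adjusted over the list alone). A median of 1.58 gave camera adjusted p = 0.000103, and adjusted p = 0.545 with an estimated correlation. Muscle genes rose in 25 and fell in 1 of 30 (25 and 1 adjusted over the list alone), with the myosin myo-1 at 51.5 ± 5.66 against 12 TPM. The median was 1.03 (camera adjusted p = 0.04997, adjusted p = 0.747 with an estimated correlation). Ribosomal protein genes rose in 72 and fell in 1 of 78 (73 and 1 adjusted over the list alone), though their median of 0.30 lay below the 0.41 of all genes. Camera called the list toward higher (adjusted p = 0.00250; adjusted p = 0.589 with an estimated correlation). Early embryo zygotic genes were higher in 8 and lower in 7 of 23 (8 and 6 adjusted over the list alone), and 2 higher and 17 lower under quantile normalization. At a median -0.11, camera gave adjusted p = 0.0531, and adjusted p = 0.545 with an estimated correlation. Other named genes were F41F3.3 (288 ± 98.9 TPM), C50F7.5 (772 ± 239 against 3.52 TPM), col-167 (337 ± 209 TPM) and dpy-4 (281 ± 145 TPM), which rose, and spex-3 (7.07 ± 4.81 against 188 TPM) and acdh-2 (1.28 ± 0.764 against 34.6 TPM), which fell. The pud-2.2 copy WBGene00017500 fell as well (28.5 ± 40.4 TPM; log2 fold change -6.01, limma adjusted p = 0.0254), a call lost without F1 deletion replicate 1 (-3.08), without control replicate 2 (-5.66) or 3 (-5.94), with the replicate block (-5.68) and with a pseudocount of 0.1 (-7.67).

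By limma, 7839 of 15519 genes were higher and 2966 lower in F1 deletion worms (median 0.41), with 5094 and 381 changed by a log2 of at least 1. Median-of-ratios scaling gave 7569 higher and 3766 lower, and quantile normalization 4014 and 6053 (median -0.15). Simulated recovery of log2 changes of 1 and 2 was 76 and 94%.

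F1 deletion worms, compared with P0 deletion worms, had more sperm and collagen mRNA. All 28 major sperm protein genes were higher (28 adjusted over the list alone). A median of 5.67 gave camera adjusted p = 3.54e-25, and adjusted p = 0.465 with an estimated correlation. Sperm and spermatogenesis genes were higher in 26 of 31 (26 adjusted over the list alone). The median was 2.00 (camera adjusted p = 2.54e-18, adjusted p = 0.465 with an estimated correlation). Cuticle collagens were higher in 91 and lower in 17 of 136 (96 and 19 adjusted over the list alone), col-133 reaching 215 ± 106 TPM (SD, n = 2) from 0.117 ± 0.0929 TPM (SD, n = 3) and col-159 reaching 625 ± 413 from 3.32 ± 0.596 TPM. Their median, 1.79, gave camera adjusted p = 2.30e-24 and adjusted p = 0.465 with an estimated correlation. Early embryo zygotic genes were lower in 17 of 23 (17 adjusted over the list alone). At a median -0.85, camera gave adjusted p = 0.000242, and adjusted p = 0.465 with an estimated correlation. Neuronal genes were lower in 23 of 35 (26 adjusted over the list alone). A median of -0.61 gave camera adjusted p = 1.61e-05, and adjusted p = 0.654 with an estimated correlation. Of 28 oocyte and eggshell genes 2 were higher and 3 lower (1 and 3 adjusted over the list alone), or 9 and 2 under median-of-ratios scaling, where camera called the list toward higher (adjusted p = 0.0407). Without that scaling camera's adjusted p = 0.570 became adjusted p = 0.913 with an estimated correlation. col-165 (3.60 ± 0.799 TPM), col-74 (1.96 ± 1.33 against 118 TPM), fip-1 (0.865 ± 0.191 against 70.5 ± 44 TPM) and cut-3 (4.41 ± 0.0354 against 161 TPM) were lower in F1. Limma called 1921 genes higher and 3677 lower (median -0.12), or 2738 higher and 2572 lower under median-of-ratios scaling (median -0.01).

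**Figure D2:**
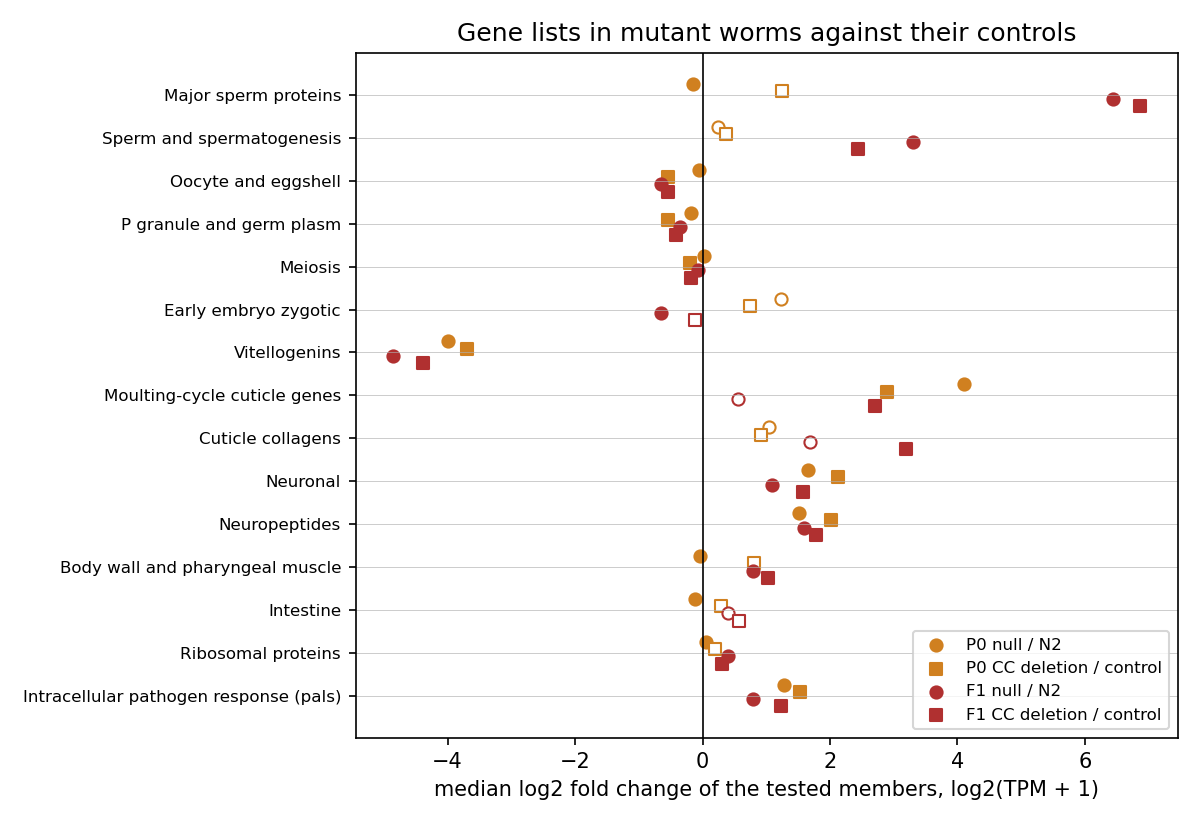
Median log2 fold change on the log2(TPM + 1) scale (x axis) of 15 gene lists (y axis) in mutant worms against their own control; circles are null against N2, squares coiled-coil deletion against the tagged control, orange P0 and red F1, and a filled symbol passed camera with its preset correlation. Major sperm proteins lay at 6.44 and 6.87 in F1 worms and at -0.15 and 1.25 in P0 worms, while vitellogenins lay between -4.86 and -3.70 in all 4 comparisons.

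The null and coiled-coil alleles were compared gene by gene over the 15052 genes tested in both tables. In P0 worms, 7011 genes were higher with both alleles (4982 for independent lists) and 847 lower with both (205 for independent lists), while 321 were higher in null and lower in deletion worms and 63 the reverse. In F1 worms, 6467 were higher with both (3681 for independent lists) and 2408 lower with both (734 for independent lists), with 31 and 83 opposite. Fold changes correlated across genes, which are not independent replicates, with Pearson's r = 0.86 and Spearman's rho = 0.82 in P0 and r = 0.86 and rho = 0.88 in F1. Of the genes called in both, 95.3% of 8242 in P0 and 98.7% of 8989 in F1 went the same way. The alleles had separate controls, but table and sequencing batch could not be told apart from allele.

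**Figure D3:**
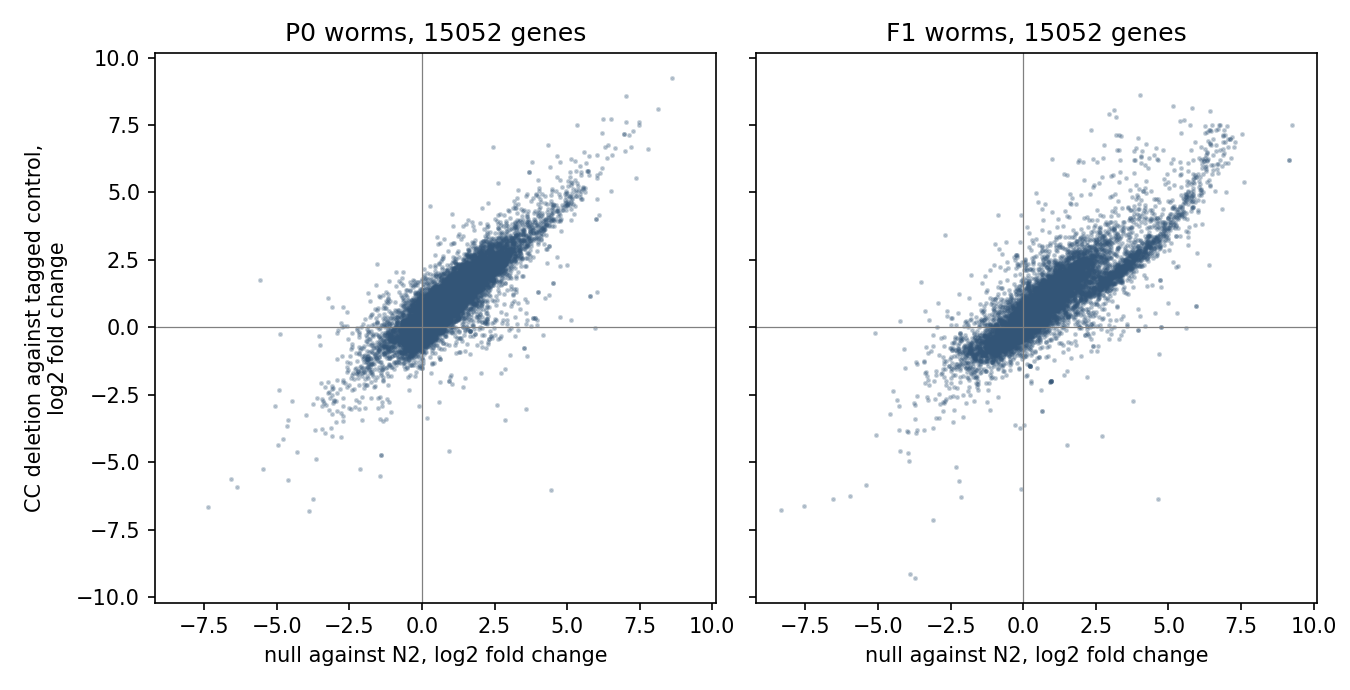
Log2 fold change on the log2(TPM + 1) scale of coiled-coil deletion worms against the tagged control (y axis) over that of null worms against N2 (x axis), for P0 worms (left) and F1 worms (right); each dot is one of 15052 genes. The cloud follows the diagonal in both panels, with Pearson's r of 0.86 in each.

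P0 and F1 worms of the same allele shared a control. For the null allele, 5671 genes were higher in both generations (4690 for independent lists) and 852 lower in both (316 for independent lists), and 1420 were higher in P0 and lower in F1. For the coiled-coil allele, 6547 were higher in both (4225 for independent lists) and 2010 lower in both (461 for independent lists). Pearson's r across genes was 0.38 for null (rho 0.45) and 0.69 for deletion worms (rho 0.78), against 0.50 and 0.44 for simulated unchanged groups with the same controls. The covariance was 0.63 for null and 1.05 for deletion worms, against 0.0301 and 0.0287 in the simulation, which made 0 shared calls on average over 20 runs. The controls were too few to split, so part of the excess may come from the shared controls.

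Another 10 lists had members in both directions. Heat shock genes rose in 8 and fell in 4 of 15 in P0 null worms, 4 and 6 of 15 in F1 null, 8 and 4 of 16 in P0 deletion and 6 and 6 of 16 in F1 deletion worms (the same counts adjusted over the list alone). Endoplasmic reticulum unfolded protein response genes rose in 17 and fell in 1 of 21 in P0 null, 9 and 9 in F1 null, 17 and 2 in P0 deletion and 11 and 4 in F1 deletion worms (17 and 1, 9 and 9, 17 and 2, 11 and 5 adjusted over the list alone). Mitochondrial unfolded protein response genes rose in 4, 2, 4 and 5 and fell in 3, 4, 3 and 2 of 12, in the same order (the same counts adjusted over the list alone). DAF-16 targets rose in 12, 10, 14 and 10 and fell in 5, 6, 2 and 4 of 21 (the same counts adjusted over the list alone). Fatty acid metabolism genes rose in 9, 8, 15 and 12 and fell in 12, 12, 7 and 8 of 28 (9, 8, 15 and 12 and 12, 12, 7 and 9 adjusted over the list alone). Intestine genes rose in 8, 14, 11 and 15 and fell in 12, 7, 8 and 6 of 26 (9, 14, 12 and 15 and 12, 7, 8 and 6 adjusted over the list alone). Germline small RNA pathway genes rose in 23, 9, 7 and 7 and fell in 6, 14, 15 and 15 of 43 (23, 9, 7 and 7 and 6, 13, 13 and 15 adjusted over the list alone). Oxidative phosphorylation genes rose in 10, 17, 7 and 16 and fell in 7, 3, 10 and 7 of 40 (8, 15, 6 and 15 and 7, 2, 9 and 7 adjusted over the list alone). Adult-stage cuticle genes rose in 7, 7, 7 and 13 and fell in 5, 3, 5 and 1 of 16 in the null and 17 in the coiled-coil table (the same counts adjusted over the list alone). Detoxification genes rose in 54 and 50 and fell in 37 and 43 of 138 in P0 and F1 null worms, and rose in 66 and 67 and fell in 33 and 31 of 136 in P0 and F1 deletion worms (53, 50, 67 and 67 and 37, 43, 33 and 31 adjusted over the list alone).

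Camera called fatty acid metabolism genes in P0 and F1 null worms (adjusted p = 6.33e-06 and 0.0106; adjusted p = 0.335 and 0.376 with an estimated correlation), intestine genes in P0 null worms (2.23e-06; adjusted p = 0.335 with an estimated correlation) and oxidative phosphorylation genes in P0 null and P0 deletion worms (2.09e-06 and 0.00147; adjusted p = 0.366 and 0.492 with an estimated correlation), each toward lower. Small RNA pathway genes were called lower in P0 deletion worms (camera adjusted p = 2.89e-05; adjusted p = 0.529 with an estimated correlation). The heat shock, endoplasmic reticulum, mitochondrial, DAF-16 and adult-stage cuticle lists did not pass in any of these 4 comparisons.

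Scaling decided the direction of several lists. Quantile normalization turned detoxification genes to 18 higher and 90 lower in P0 null, 15 and 87 in F1 null, 18 and 85 in P0 deletion and 16 and 75 in F1 deletion worms. Camera tests against all genes (medians 0.44 in P0, 0.32 in F1 null worms), so lower need not mean a fall. Its sign differed from the median and mean for detoxification genes there (medians 0.12 and 0.11). Camera gave lower (adjusted p = 2.40e-06 and 0.0407, or 0.137 and 0.374 with an estimated correlation). The same held for meiosis genes in P0 null worms (12 higher and 4 lower of 35; 10 and 4 adjusted over the list alone; median 0.03, camera lower, adjusted p = 0.000208; adjusted p = 0.335 with an estimated correlation), which were 0 higher and 27 lower under median-of-ratios scaling. It held for ribosomal protein genes in P0 null worms as well (8 higher and 1 lower of 78; 3 and 0 adjusted over the list alone; median 0.06, camera lower, adjusted p = 0.000866; adjusted p = 0.603 with an estimated correlation), which were 3 higher and 69 lower under median-of-ratios scaling. That scaling also gave 3 higher and 21 lower small RNA pathway, 0 and 33 oxidative phosphorylation, 0 and 17 P granule, 38 and 57 detoxification, 9 and 19 muscle, 4 and 5 heat shock and 2 and 7 mitochondrial genes in P0 null worms. In P0 deletion worms it gave 5 and 29 small RNA pathway, 4 and 25 oxidative phosphorylation, 3 and 7 NuRD and 3 and 6 mitochondrial genes. Muscle genes in P0 null worms (10 higher and 11 lower of 30, the same adjusted over the list alone) had a median of -0.03 and a mean of 0.17, with camera lower (adjusted p = 9.47e-05; adjusted p = 0.490 with an estimated correlation). Small RNA pathway genes had medians of -0.02 and -0.07 and means of 0.15 and 0.09 in F1 null and F1 deletion worms, and histone methylation genes a median of -0.10 and a mean of 0.08 in P0 deletion worms, with camera lower each time (adjusted p = 0.0236, 0.000514 and 0.000807; adjusted p = 0.530, 0.546 and 0.529 with an estimated correlation). In lists that did not pass, camera's sign also differed from median or mean. It did for heat shock and mitochondrial genes in all 4 comparisons with a control. In P0 null worms it did for sperm, collagen, antimicrobial, DAF-16, small RNA, adult-stage cuticle and synMuvB genes. In F1 null worms it did for endoplasmic reticulum, DAF-16, intestine and adult-stage cuticle genes. In P0 deletion worms it did for NuRD, sperm, collagen, detoxification, fatty acid, intestine and adult-stage cuticle genes. In F1 deletion worms it did for early embryo, detoxification, fatty acid and oxidative phosphorylation genes. None of the 17, 20, 13 and 17 lists camera called in these comparisons kept its call with an estimated correlation.

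Signal opposite to abundant genes varied with group, a measure chosen after the values were seen. Summed over 10 antisense gene models, opposite-strand TPM was 8.23 ± 0.579% of that of the sense genes in the tagged control (SD, n = 3), 4.99 ± 3.07% in P0 deletion (SD, n = 3) and 0.851 ± 0.407% in F1 deletion worms (SD, n = 2). The single P0 deletion libraries gave 8.06, 1.93 and 4.98%. In the null table it was 0.342 ± 0.000715% in N2, 0.489 ± 0.0915% in P0 and 1.14 ± 0.233% in F1 worms (SD, n = 2 each). T27A10.8 (X, 3572379 to 3572566), antisense to vit-3, stood at 618 ± 16 TPM in the control and was listed at 0 in F1 deletion worms, and F59D8.3 (X, 3563816 to 3563991) stood at 570 ± 36 TPM, 9.49 ± 12.8 TPM in P0 and at 0 in F1 deletion worms. F59D8.3, named by the rule for genes, shares 150 bases with vit-4 on the other strand, too few to be among the 10 models. No test separated transcription from reads of the wrong strand, and a difference in library preparation or strand handling was not excluded. It would be confounded with genotype in F1 deletion worms, less so in P0, where replicate 1 matched the control. Whether quantification used strand is not given in the sources used here, so calls for these and for other overlapping named genes (clec-97, col-39, col-74, col-92, cut-3, dpy-4, fip-1, msp-33, T13F3.6, Y47G6A.33, col-159, his-73, msd-2, msp-31 and acdh-2) are uncertain. Of the tested genes with at least 50% of their exonic bases opposite to another gene, 25 were higher and 33 lower in F1 deletion worms by limma (median -0.29), against 7814 and 2933 of 15415 other genes (median 0.41). The same genes were 23 higher and 14 lower in P0 deletion worms (median 0.10, others 0.44), and in the null table such genes were 26 and 11 in P0 (0.20, others 0.44) and 27 and 16 in F1 worms (0.24, others 0.32). Without P0 deletion replicate 2, the library with the least opposite-strand signal of its group, limma called 10328 genes in P0 deletion worms against the control and 4994 in F1 against P0.

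Genes of the X chromosome stood out in 1 comparison with a control. In P0 deletion worms 1637 of 2255 X-linked genes were higher and 223 lower (1649 and 228 adjusted over the list alone). Their median, 1.05, gave camera adjusted p = 0.000149 and adjusted p = 0.0383 with an estimated correlation. The X set did not pass in P0 null (median 0.92, camera adjusted p = 0.190), F1 null (0.51, 0.762) or F1 deletion worms (0.75, 0.110). Within 500 kb of mbd-2, 117 of 227 genes (51.5%) were called in P0 null worms against 68.5% elsewhere (Fisher's exact test, two-sided, adjusted p = 1.03e-06), and 78.9% against 69.8% in F1 against P0 null (adjusted p = 0.00821). The same exact test did not pass in the other 4 comparisons (adjusted p = 0.144, 0.0629, 0.504 and 0.504).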

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

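In this part the test for embryos inside P0 worms, with its 20 regulators, was written down after the main results but before the values of those genes were seen, and the tests of male worms, scaling, germline timing, larval delay, germline share, ribosomal RNA and other splits were chosen only after the results were seen. The results below stand out because the null effect and the coiled-coil effect of the same generation differed in a limma test of the difference, null minus coiled-coil, on the log2(TPM + 1) scale; as each allele has its own table and batch, a difference between tables cannot be told apart from a difference between alleles.

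In P0 worms 4455 of 15052 genes differed between the alleles, 3057 with a higher and 1398 with a lower effect in null worms, against 1190 and 2177 under median-of-ratios scaling and 1127 and 937 under quantile normalization, and against 2661 in all without P0 null replicate 2 and 2736 without N2 replicate 2. mbd-2 differed by -1.82, as it fell further in null worms. The histone gene his-73 differed by 4.45, with 16.9 TPM in P0 null and 0.59 TPM in P0 deletion worms (limma adjusted p = 0.0180), a call lost with a pseudocount of 0.1 and when any 1 N2 or P0 null library was left out. The non-coding RNA linc-17 differed by 4.38 (44.9 against 0.735 TPM in N2; 1.42 against 0.867 TPM in the coiled-coil table). The F-box gene fbxb-97 differed by 4.05 (14.6 against 0.935 TPM in N2; 0.63 against 2.32 TPM). The ribonuclease H gene rnh-1.3 differed by 3.67, with 150 against 10.3 TPM in N2 and 13.4 against 12.9 TPM in the coiled-coil table. 1 of 2 genes named nspc-2 (WBGene00044337) differed by -7.31, being listed at 0 in P0 null and at 33.2 TPM in P0 deletion worms, while its copy WBGene00044357 went from 0 in N2 to 62.6 TPM in P0 null worms, so the difference is uncertain, and its call (limma adjusted p = 0.0330) was lost under quantile normalization, with the replicate block and when any 1 N2, P0 null or P0 deletion library was left out. The protease gene cpr-2 differed by -3.14 (1.23 TPM in P0 null, 18.7 TPM in P0 deletion worms). The collagen col-92 differed by -2.98, with 5.45 against 43.3 TPM in N2 and 2.49 against 2.1 TPM in the coiled-coil table. msp-59 differed by -2.95, with 3.55 against 9.64 TPM in N2 and 4.29 against 0.0933 TPM in the coiled-coil table (limma adjusted p = 0.0293), a call lost without N2 replicate 2 (-1.91), either P0 null library, control replicate 2 or 3, or P0 deletion replicate 3.

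In F1 worms 2593 of 15052 genes differed, 1087 with a higher and 1506 with a lower effect in null worms, against 1115 in all without N2 replicate 1, 1299 without F1 null replicate 1, 1691 with the replicate block, 1229 with a mean of at least 5 TPM, and 422 higher and 1514 lower with a pseudocount of 0.1. mbd-2 differed by -2.03. linc-17 differed by 4.78 (66 TPM in F1 null, 1.59 TPM in F1 deletion worms). his-73 differed by 3.99 (23.1 and 2.61 TPM; limma adjusted p = 0.0499), a call lost with a pseudocount of 0.1, without the filter, in a fit of only the groups compared, with the replicate block and when any 1 library but F1 deletion replicate 2 was left out. fip-1, listed at 0 in both controls, differed by 4.10 (31.3 and 0.865 TPM). The lectin clec-209, which has near-identical copies, differed by 3.73 (278 against 178 TPM in N2, 38.6 against 334 TPM in the coiled-coil table). The collagens dpy-14 (-6.10; 0.325 against 7.79 TPM in N2, 21.7 against 1.22 TPM), dpy-13 (-4.95; 21.9 and 270 TPM in F1) and dpy-4 (-4.61; 27.1 and 281 TPM in F1) had lower effects in null worms, as did dao-2 (-5.05; 3.95 and 54.9 TPM in F1). The calls for dpy-13 and dpy-4 (limma adjusted p = 0.0336 and 0.0312) were lost in a fit of only the groups compared, with the replicate block and when any 1 N2 or control library, or F1 deletion replicate 2, was left out.

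Sperm transcripts were higher in F1 worms of both alleles, with major sperm proteins summing to 11258 TPM in F1 null worms against 121 TPM in N2, and to 4088 TPM in F1 deletion worms against 2.13 TPM in the control. Scaling is argued against: the median log2 change of these genes was 6.43 in null and 6.87 in deletion worms after median-of-ratios scaling. Male worms cannot be excluded: over all 11 male neuron and tail markers the medians were 0.56 (95% bootstrap interval 0.13 to 2.33) and 0.66 (0.09 to 1.88), and over the members that passed the low-value filter, the test as first run, 1.52 and 1.88, while pkd-2 stood at 0.095 and 0.075 TPM and nlp-41 at 42.8 and 28.8 TPM. P0 worms had like medians over all members, 0.54 in null and 0.52 in deletion worms, with nlp-41 at 26.7 and 31.1 TPM. F1 worms collected earlier in germline development also stay open. The oocyte, yolk and early embryo medians of F1 against P0 were all below 0, but 2 intervals reached past 0. These were for oocyte genes in the coiled-coil table (-0.0369, interval to 0.01) and yolk genes in the null table (-0.91, -1.49 to 0.23). An effect of mbd-2 genotype, of the worms or their parents, was not tested apart from these explanations.

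Camera called neuronal and moulting-cycle cuticle lists higher in P0 worms of both alleles, but neither kept its call (neuronal adjusted p = 0.361 in null and 0.492 in deletion worms, moulting-cycle adjusted p = 0.366 and 0.316, with an estimated correlation), while the early embryo zygotic list passed in neither (camera adjusted p = 0.0851 and 0.790; adjusted p = 0.490 and 0.920 with an estimated correlation). A candidate explanation is that P0 worms held embryos past the early stages: 20 regulators of mid and late embryos, none of them chosen from these data, stood above the median of all genes by 1.72 in P0 null and 1.42 in P0 deletion worms (19 and 18 of 20 higher by limma, with no list test), but by -0.31 and 0.09 in F1 worms. Such embryos would leave F1 worms unexplained, where camera also called neuronal genes higher in both alleles (adjusted p = 0.000152 and 0.000103; adjusted p = 0.376 and 0.545 with an estimated correlation) and moulting-cycle genes in deletion worms (adjusted p = 1.11e-06; adjusted p = 0.376 with an estimated correlation). A delay of P0 null worms to the larval stage at which sperm is made is argued against. Their major sperm protein median was -0.15 (interval over genes -0.31 to -0.08). In P0 deletion worms a delay stays open (median 1.25, 0.95 to 1.46). Their sperm protein sum, 51.2 TPM, lay below 74.3 TPM in P0 null worms, but the controls held 2.13 and 121 TPM. A smaller germline raising all somatic transcripts alike is argued against. Neuronal less intestine medians were 1.78 and 1.83 in null and deletion worms (intervals 1.12 to 2.52 and 1.26 to 2.57). An effect of mbd-2 genotype itself stays open and was not tested apart from these.

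Most called genes were higher in the mutants than in the controls. The lower ribosomal RNA share in the mutants is argued against as the whole cause, since after its removal the medians of all genes were 0.33, 0.19, 0.38 and 0.34 in P0 null, F1 null, P0 deletion and F1 deletion worms. The scaling choice stays open in part: median-of-ratios scaling left 62.6, 64.6, 65.2 and 66.8% of called genes higher in the same order, and quantile normalization, which forces equal distributions, cannot test the split. For the 10775 genes called in P0 deletion worms, 1 of the 10 splits of the 6 libraries gave as many genes and the highest of the others gave 0, but 10 splits are too few for a share under 0.05.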

How the results depend on the processing

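Of the alternatives, removal of ribosomal RNA was chosen only after the results were seen. For each gene named by the rule the change was recomputed under every alternative that applied, 4523 recomputations of 354 gene results: 4446 kept direction and call, 70 lost the call and 7 reversed. The reversals were all in P0 null worms: under quantile normalization nos-1 went to -0.017, cpg-1 to 0.051, syp-1 to -0.25, coh-3 to -0.20 and rpl-11.1 to 0.025, and under median-of-ratios scaling coh-3 went to -0.014 and cox-14 to -0.058; the cause was not tested. Lost calls were those of mbd-2 in F1 against P0, of pud-2.2 against the control, of nos-1, ucr-2.1, cox-14, jmjd-3.1 and syp-1 under a scaling, and of his-73, nspc-2, msp-59, dpy-13 and dpy-4 between the alleles.

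Counts fell by construction where fewer genes could pass. A log2 fold change of at least 1 left 5239 (P0 null), 5568 (F1 null), 4287 (F1 against P0 null), 5590 (P0 deletion), 5475 (F1 deletion) and 2353 (F1 against P0 deletion) genes, and 714 (P0) and 1404 (F1) between the alleles. A mean of at least 5 TPM left 7730 (F1 null), 7089 (P0 deletion), 6835 (F1 deletion), 2958 (F1 against P0 deletion) and 1229 (between the alleles in F1) genes, and 4905 (P0) and 5583 (F1) genes called the same way with both alleles. Quantile normalization left 2064 genes between the alleles in P0; the cause was not tested. Of P0 null calls, quantile normalization kept 5417 of 10786 in direction and turned 1173, and median-of-ratios scaling kept 7646 and turned 451.

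With an estimated correlation camera called 0 lists in each of the 6 comparisons, against 17, 20, 18, 13, 17 and 14 with the preset one. fry, which tests whether a list moves on balance one way, called 23, 28, 27, 24, 27 and 20 lists in the same order; the cause was not tested. The call for the X chromosome in F1 against P0 deletion worms was lost (adjusted p = 0.0719).

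Leaving out each library in turn gave 9269 to 9871 genes (P0 null), 10093 to 10381 (F1 null), 9759 to 10171 (F1 against P0 null), 9845 to 10387 (P0 deletion), 9619 to 10344 (F1 deletion) and 4199 to 5472 (F1 against P0 deletion). Between the alleles it gave 2661 (without P0 null replicate 2; 2736 without N2 replicate 2) to 4897 in P0, and 1115 (without N2 replicate 1) to 3263 in F1, with 1299 and 1520 without F1 null replicates 1 and 2, 1593 without N2 replicate 2 and 1714 without control replicate 2. A group left with 1 library is assumed to vary like the others, and the cause was not tested.

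Replicate numbers did not pair the libraries: correlations of same-numbered libraries' deviations were -0.005 to 0.017 in the null table and -0.106 to 0.043 in the coiled-coil table. With the replicate block, counts were 10616, 11538, 10907, 10307, 9992 and 4190 in the 6 comparisons, 3486 between the alleles in P0 and 1691 in F1, and 5 of 354 gene calls were lost. Depth, unknown for TPM, limits what can be said of genes near 0.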

Other observations

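In this part the gene name families were planned, the 20 regulators of embryos were named after the main results but before their own values were seen, and the opposite-strand gene models were chosen only after the results were seen.

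Some gene name families outside the fixed lists passed camera with its preset correlation, and none of those named here kept its call with an estimated correlation. F-box genes of the fbxb family were lower in F1 worms, 61 of 69 with 2 higher in null (the same counts adjusted over the list alone; median log2 fold change -1.05; camera adjusted p = 9.11e-19; adjusted p = 0.470 with an estimated correlation) and 23 of 66 with 1 higher in deletion worms (13 and 0 adjusted over the list alone; median -0.35; camera adjusted p = 2.85e-08; adjusted p = 0.490 with an estimated correlation). In P0 worms 42 of 69 fbxb genes were higher in null and 28 of 66 in deletion worms, with 4 lower (limma), but quantile normalization turned these to 8 higher and 46 lower and 5 higher and 49 lower, and the family did not pass (40, and 27 and 4, adjusted over the list alone; camera adjusted p = 0.321 and 0.398; adjusted p = 0.841 and 0.930 with an estimated correlation). The sdz genes, named for SKN-1-dependent zygotic transcripts, were lower in F1 worms, 18 of 25 with 1 higher in null (18 and 1 adjusted over the list alone; median -1.19; camera adjusted p = 7.00e-07; adjusted p = 0.470 with an estimated correlation) and 11 of 24 with 2 higher in deletion worms (9 and 1 adjusted over the list alone; median -0.46; camera adjusted p = 5.02e-05; adjusted p = 0.436 with an estimated correlation). Nuclear pore genes of the npp family were lower in 20 of 26 cases in both F1 groups, with 0 and 1 higher by limma (20 and 21 lower adjusted over the list alone; camera adjusted p = 1.32e-05 and 3.94e-07; adjusted p = 0.470 and 0.436 with an estimated correlation). They were lower in P0 deletion worms as well, 16 of 26 with 1 higher (the same counts adjusted over the list alone; camera adjusted p = 5.10e-07; adjusted p = 0.400 with an estimated correlation), but 9 higher and 2 lower in P0 null worms, where the family did not pass (5 and 2 adjusted over the list alone; camera adjusted p = 0.0538; adjusted p = 0.667 with an estimated correlation) and median-of-ratios scaling turned the counts to 1 higher and 21 lower.

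Cuticlin-like cutl genes were higher in P0 worms, 23 of 23 in null (23 adjusted over the list alone; median 2.24; camera adjusted p = 1.68e-05; adjusted p = 0.565 with an estimated correlation) and 23 of 24 in deletion worms (24 adjusted over the list alone; median 2.08; camera adjusted p = 3.52e-05; adjusted p = 0.381 with an estimated correlation). Globin genes of the glb family were higher in 28 of 29 in P0 null (28 adjusted over the list alone; median 1.25; camera adjusted p = 0.00577; adjusted p = 0.652 with an estimated correlation) and 30 of 30 in P0 deletion worms (30 adjusted over the list alone; median 1.67; camera adjusted p = 0.000219; adjusted p = 0.381 with an estimated correlation). Globin genes were called higher in F1 worms too, 26 of 29 in null and 28 of 30 in deletion worms (the same counts adjusted over the list alone; camera adjusted p = 0.00238 and 0.000402; adjusted p = 0.470 and 0.436 with an estimated correlation). So were cutl genes in F1 deletion worms, 20 of 24 (21 adjusted over the list alone; camera adjusted p = 0.00307; adjusted p = 0.436 with an estimated correlation), while in F1 null worms 15 of 23 were higher and the family did not pass (15 adjusted over the list alone; camera adjusted p = 0.0524; adjusted p = 0.470 with an estimated correlation). The 20 regulators of mid and late embryos were lower in F1 than in P0 worms in 18 cases in the null table (median -1.93) and 17 in the coiled-coil table (median -1.33), with none higher in either by limma.

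Opposite-strand signal varied with group inside the coiled-coil table. F31C3.14, antisense to the ribosomal RNA gene rrn-3.1 at I, 15067668 to 15068355, amounted to 2.31 ± 0.133% of its partner in the control (SD, n = 3), 1.02 ± 0.809% in P0 deletion (SD, n = 3) and 0.115 ± 0.00257% in F1 deletion worms (SD, n = 2), against 0.0676 ± 0.000567% in N2 (SD, n = 2). T27A10.8 amounted to 12 ± 0.385% of vit-3 in the control, 7.30 ± 4.86% in P0 deletion worms and 0.283 ± 0.0239% in N2, and F59D8.3 to 11.9 ± 1.28% of vit-4 in the control, 4.92 ± 4.78% in P0 deletion worms and 0.366 ± 0.0816% in N2. Both were listed at 0 in P0 null, F1 null and F1 deletion worms. No explanation of this difference was tested. A difference in library preparation or strand handling, confounded with genotype in F1 but less so in P0 deletion worms, was not excluded.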
